A study of Gallus gallus with 24 samples.

How the data were processed

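Gene expression was measured in the combined retina and pigment epithelium of 24 eyes, 1 array per eye. Per the labels' protocols, a translucent white goggle was fitted over 1 eye of each chick at the start of the light phase, on alternate sides, and the retina was taken 6 h or 3 d later. Per the labels' protocols, 3 µg of total RNA per eye was amplified, biotin-labelled and hybridised to Affymetrix GeneChip Chicken Genome arrays, and scans were collected with GCOS version 1.4. Per the submitters' processing notes, GCOS and RMA were used, without their roles. The deposited values are 1 linear intensity per probe set and array, checked from their range and from a 2% trimmed mean of 150.03 on each of the 24 arrays. Log2 values of RMA would look different, so which software made the table is not given in the sources used here. Because the values were linear, log2 was taken first, as the plan had foreseen.

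Of 38535 probe sets, 96 Affymetrix controls were removed, 16 was added to each signal before log2, and probe sets with a mean below the 30th percentile of the remaining 38439 (a signal of 13.4) were left out, which left 26907. The 57 reporter probe sets, which match no chicken gene, gave the background: their median signal was 3.25 and their 95th percentile 22.8, and 14.3% of the tested probe sets had a mean below the latter. The platform's annotation gave 1 gene for 27168 probe sets, several for 177 and none for 11094, and 26863 symbols were updated by gene ID from the RefSeq table of assembly GRCg7b, used for names only. Tested were 20695 probe sets with 1 gene and 6093 with no gene name, and no gene was named from a probe set with several.

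Arrays were grouped by eye and time into 4 groups of 6. Linear models were fitted to all 24 arrays with limma 3.58.1 in R 4.3.3, with 4 group means, 20 residual degrees of freedom and moderated variances (eBayes), and p-values were adjusted over all probe sets tested with the Benjamini-Hochberg method at a threshold of 0.05. The comparisons were goggled against open eyes at 6 h, at 3 d and over both times, the difference of the goggle effect between the times, and 3 d against 6 h in open and in goggled eyes. In the second fit the chick was a fixed block (10 residual degrees of freedom). Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The scripts were tested on simulated data: with 50 probe sets changed per size at 3 d among 26907, limma called 40% of those changed by 0.5 on the log2 scale, 78% at 0.75, 92% at 1 and 100% at 1.5, and 4 unchanged ones, and with the block 54%, 90%, 94%, 100% and 13 unchanged ones.

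Arrays of equal replicate number at a time were taken as both eyes of a chick. Per the labels' protocols both eyes of 6 chicks per time were used, but the labels do not say which arrays pair. The pairing was checked with the correlation of the deviations from the group means. It was 0.229 to 0.424 for the 6 pairs at 6 h and 0.102 to 0.445 at 3 d, all over the 0.1 set as the minimum, with means of 0.345 and 0.275 against -0.069 and -0.055 for arrays of other chicks. The numbered pairing had the highest mean of all 720 pairings at each time (exact permutation p = 0.00139, the smallest possible). All 6 open eyes at 6 h and 5 of 6 at 3 d correlated best with the goggled eye of the same number. The exception, 3 d open replicate 2, correlated best with 3 d goggled replicate 3 (0.291, against 0.199 with goggled replicate 2). In turn, 3 d goggled replicate 3 correlated best with open replicate 2, against 0.102 with open replicate 3. The pairing is thus inferred, and least sure for these chicks.

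Before the data were examined, 39 gene lists were fixed, 26 of pathways and 13 of cell or tissue markers, and tested with limma's camera (preset correlation 0.01, two-sided) on the brightest probe set of each of 11117 genes, for lists with 5 or more tested members, adjusted over the lists of a comparison. Beside it stood camera with an estimated correlation and fry and, added after seeing the data, exact sign-flip tests of list means over chicks. Lists that passed in no comparison are not described further, except where a member or an alternative is. The genes named in the text follow a rule fixed before the data were examined: the 10 highest and 10 lowest log2 changes among genes past the threshold, in both fits, the 5 smallest p where fewer than 10 passed, up to 4 passing members per list and direction, and 16 genes known from work on myopia or the retina, given for the goggle comparisons whatever their result.

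The alternatives were the block as a fixed or random term, no filter or one at the 50th percentile, trended robust variances, array weights, quantile normalization, median centring, an adjusted p under 0.10, a 1.2-fold minimum, 1 probe set per gene, only the 12 arrays compared, and leaving out each array. Added after seeing the data were other offsets, the signal of a W-linked probe set as a covariate, leaving out both eyes of each chick, leaving out 3 arrays apart on the second principal component (11.6% of the variance), lists without these or without the 2 arrays highest in muscle markers, lists under the other scalings, and the sign-flip tests. Up to 100 other splits of the samples were fitted per comparison. Unnamed probe sets, 406 of those called in open eyes and 743 in goggled eyes between the times, are counted but not described.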

Results

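Gene expression was measured in the retina together with its pigment epithelium in 24 eyes of 12 chicks, with 1 Affymetrix GeneChip Chicken Genome array per eye. Each chick wore a translucent white goggle over 1 eye, which blurs the image and leads to form-deprivation myopia, an eye that grows too long, and the fellow eye stayed open. The goggle was worn for 6 h by 6 chicks and for 3 d by 6 others, which gave 4 groups of 6 arrays: open and goggled eyes at 6 h and at 3 d. The deposited values were linear signal intensities per probe set, and 26907 of 38439 probe sets were bright enough to be tested. The median signal of an array was 40.4 ± 3.41 (SD, n = 6) in open eyes at 6 h, 39.7 ± 3.04 in goggled eyes at 6 h, 35.6 ± 2.68 in open eyes at 3 d and 32.5 ± 2.24 in goggled eyes at 3 d. The 3'/5' signal ratio of the actin control probe sets, a sign of RNA integrity, ranged from 2.40 to 5.05, with group means of 3.46 ± 0.878, 3.66 ± 0.644, 3.69 ± 0.224 and 3.85 ± 0.614 in the same order. The number of arrays limits the precision of every value given here.

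Goggled and open eyes at 3 d were compared to find the genes that respond to sustained loss of form vision. VIP and UTS2B were lower in the goggled eye than in the open eye of all 6 chicks. VIP encodes vasoactive intestinal peptide, a neuropeptide of a class of amacrine cells, and its signal was 466.8 ± 62.5 (SD, n = 6) in open eyes and 232.9 ± 26.3 in goggled eyes. UTS2B encodes a peptide related to the vasoactive hormone urotensin 2, and its signal was 122.2 ± 19.4 in open eyes and 63.3 ± 5.98 in goggled eyes. VIP fell by 0.95 on the log2 scale (SE 0.15, lower in 6 of 6 chicks, limma adjusted p = 0.0121 with Benjamini-Hochberg) and UTS2B by 0.79 (SE 0.11, lower in 6 of 6, adjusted p = 0.00266). These were the 2 probe sets past an adjusted p of 0.05, and 1448 had an unadjusted p under 0.05, against 1345 that chance would give. With the chick as block the same 2 were called (limma adjusted p = 0.00171 for VIP and 0.0222 for UTS2B), with 2395 at an unadjusted p under 0.05, and with a random block 4 were called. UTS2B lost its blocked call with only the 12 arrays compared (adjusted p = 0.288) and without both eyes of any chick but replicate 2 (0.0515 to 0.167). After quantile normalization the UTS2B difference was -0.70 with a limma adjusted p of 0.058 (lower in 6 of 6 chicks before normalization), and 1 probe set was called. VIP missed the threshold without 3 d control replicate 2, 3 d control replicate 5 or 3 d goggled replicate 4 (limma adjusted p = 0.0616, 0.0591 and 0.0631), each leaving 1 call, and without 3 arrays apart on the second principal component (0.215, with 2 calls). UTS2B kept its call there, and without 3 d control replicate 1 there were 4 calls.

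**Figure D1:**
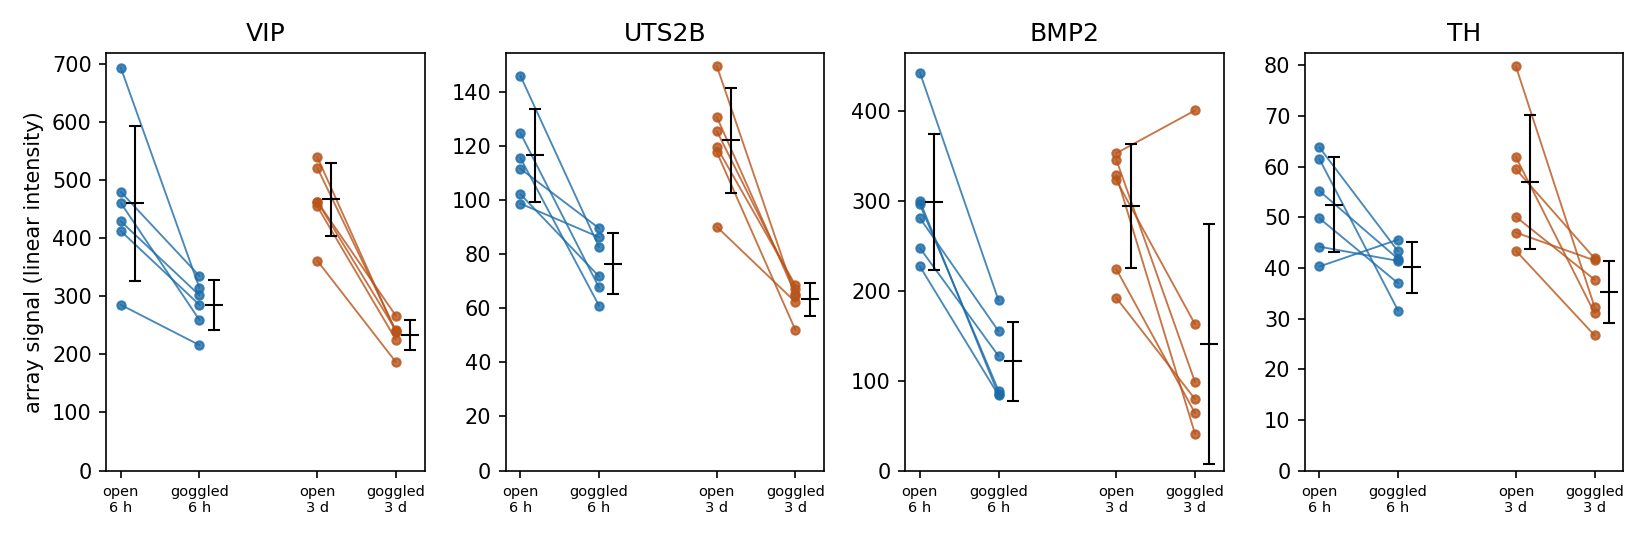
Array signal (linear intensity) of VIP, UTS2B, BMP2 and TH in open and goggled eyes at 6 h and at 3 d, with lines joining the eyes of a chick and bars for the mean ± SD of 6 arrays. VIP and UTS2B were lower in the goggled eye of all 12 chicks, and BMP2 in 11 of 12.

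Of the genes chosen before the data were examined, several others had lower values in goggled eyes at 3 d without passing the test over all genes. TH, the enzyme that limits dopamine synthesis in amacrine cells, had a signal of 57.0 ± 13.3 (SD, n = 6) in open eyes and 35.2 ± 6.14 in goggled eyes, and was lower in 6 of 6 chicks (log2 -0.50, limma adjusted p = 0.527). GCG, which encodes proglucagon and in the chick retina marks a class of amacrine cells, was 436.5 ± 44 against 321.1 ± 31.4, also lower in 6 of 6 (log2 -0.42, limma adjusted p = 0.754). BMP2, a secreted bone morphogenetic protein, was 294.7 ± 68.6 against 141.2 ± 134 and lower in 5 of 6 (log2 -1.29, limma adjusted p = 0.622). The exception was goggled replicate 3, with a BMP2 signal of 401.1 against 40.9 to 163 in the other goggled eyes, and this array also had the highest mean of choroid, sclera and vessel markers of its group (7.68 on the log2 scale, against 5.83 to 6.04 in the others). DUSP4, a phosphatase induced by growth factor signalling and among the genes with the smallest p, was 62.6 ± 13.3 against 34.4 ± 10.4 and lower in 5 of 6 (log2 -0.65, limma adjusted p = 0.381). Of the other genes with the smallest p, log2 differences were -0.58 for WWC2, -0.42 for ACOX2, -0.56 for GDAP1, -0.79 for SPIRE1, -0.47 for GNL2 and -0.55 for TRAPPC9, each lower in 6 of 6. EDEM3 (log2 -0.74, lower in 6 of 6) lay below the background level of the arrays, as did GDAP1 (18.9) and GNL2 (22.1) in goggled eyes. The remaining chosen genes differed less: EGR1 -0.22, RBP4 -0.16, TGFB2 0.01, NPY 0.01, CRY1 0.05, PENK 0.13, NOG 0.13, ALDH1A2 0.14, CRABP1 0.17, DRD4 0.17 and EDNRB 0.36 on the log2 scale. The ALDH1A2 value rested on single arrays. Its signal was 571.3 in goggled replicate 3 against 41.5 to 65.8 in the other goggled eyes, and 246.6 in open replicate 2 against 32.6 to 78.8 in the other open eyes.

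Neuropeptide genes as a group had lower values in goggled eyes at 3 d. Of 21 tested, 15 had lower values and 6 higher, with a median log2 difference of -0.11. VIP and UTS2B fell and 19 did not pass over all genes, while adjusted over the list alone VIP, UTS2B and GCG fell and NTS, which encodes neurotensin, rose (log2 0.44). The nociceptin precursor PNOC (log2 -0.45) and the C-type natriuretic peptide CNP3 (log2 -0.84) did not pass. The list passed limma's camera test at an adjusted p of 0.00137 (lower in 6 of 6 chicks as a list mean), and at an adjusted p = 0.0404 with an estimated correlation. The latter held after quantile normalization (adjusted p = 0.0473, median log2 -0.04), but not with the chick as block (adjusted p = 0.316 with an estimated correlation), after median centring (0.332, median log2 -0.06) or without the 3 arrays apart on the second principal component (0.0596). Of the 8 lists that camera called at 3 d with its preset correlation, this was the only one that held with an estimated correlation in the fit without the block, and with the block the amacrine markers were the only one.

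Markers of amacrine cells, the inhibitory interneurons of the inner retina, had lower values as well and passed camera as a list with its preset correlation. Of 20 tested, 14 had lower and 6 higher values, and VIP fell over all genes while 19 did not pass. Their median log2 was -0.09, or -0.08 after quantile normalization and -0.03 after median centring. Adjusted over the list alone 4 fell: VIP, TH, GCG and GAD2, an enzyme of GABA synthesis (log2 -0.29). The somatostatin gene SST1 (log2 -0.41) and the transcription factor TFAP2A (log2 -0.44) did not pass. Camera gave an adjusted p of 1.16e-04 (list mean lower in 6 of 6 chicks), against an adjusted p = 0.225 with an estimated correlation, or 0.0353 with the chick as block and an estimated correlation. Genes of GABA and glycine signalling had lower values in 17 of 22 (median log2 -0.12, camera adjusted p = 0.0176, list mean lower in 6 of 6 chicks, but adjusted p = 0.225 with an estimated correlation), with 1 member, GAD2, lower when adjusted over the list alone. Without the 3 arrays that stood apart on the second principal component, camera's adjusted p was 0.0976 for the amacrine markers, with a median of 0.003472 on the log2 scale, and 0.139 for the GABA and glycine genes. Bipolar cell markers and ion channel genes, which camera did not call at 3 d, also had list means lower in 6 of 6 chicks.

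Lists of energy metabolism passed camera at 3 d with its preset correlation, but not with an estimated correlation or in fry. Of 45 nuclear genes of oxidative phosphorylation, 39 had higher values in goggled eyes (median log2 0.09; NDUFS6 0.24, NDUFB6 0.24, SDHD 0.21 and NDUFC2 0.20). Of 30 genes of glycolysis and the response to low oxygen, 24 had lower values (log2 -0.21 for GAPDH, -0.20 for ENO1, -0.17 for GPI and -0.14 for LDHA). Their median log2 was -0.11, or -0.06 after quantile normalization and -0.05 after median centring. No single member passed, over all genes or adjusted over the list alone. Camera's adjusted p was 4.75e-05 for oxidative phosphorylation (list mean higher in 5 of 6 chicks, adjusted p = 0.556 with an estimated correlation) and 0.00137 for glycolysis (lower in 5 of 6, adjusted p = 0.225 with an estimated correlation). Fry gave adjusted p of 0.433 and 0.143. Genes of cholesterol and fatty acid synthesis had higher values in 18 of 27 (median log2 0.09; NSDHL 0.36, SQLE 0.24, FDFT1 0.23 and, against the rest, CYP51A1 -0.47). Their camera adjusted p was 0.0458 (higher in 6 of 6 chicks, adjusted p = 0.225 with an estimated correlation), with 0 members past limma's test adjusted over the list alone and 3 at an unadjusted p under 0.05. The lipid list lost its call after quantile normalization, with a camera adjusted p of 0.0945 (median log2 0.10, higher in 6 of 6 chicks), and after median centring, with 0.0734.

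Most light-sensing genes had lower values in goggled eyes at 3 d. Of 25 genes of rod and cone phototransduction, 18 were lower, including GNAT1, the rod transducin subunit (log2 -0.40), and SLC24A1 (log2 -0.35), with a median of -0.12 and a camera adjusted p of 0.0458 (list mean lower in 4 of 6 chicks, adjusted p = 0.587 with an estimated correlation, 0.0502 with the chick as block). Markers of rods and cones went the same way, with 12 of 15 lower (median log2 -0.11, list mean lower in 5 of 6 chicks). Their camera adjusted p was 0.0751, or 0.0197 after quantile normalization (adjusted p = 0.361 with an estimated correlation) and 0.0494 after median centring (adjusted p = 0.560 with an estimated correlation). Of 7 opsins outside image-forming vision, 6 were lower, including OPN4, or melanopsin (log2 -0.38), OPNP (log2 -0.28) and OPN5 (log2 -0.19), with a camera adjusted p of 0.0413 (lower in 5 of 6 chicks, adjusted p = 0.225 with an estimated correlation, 0.0552 with the chick as block). Of the retinoid cycle of the pigment epithelium, LRAT, which makes retinyl esters, was lower by a log2 difference of -0.56 and was the only one of 11 members that fell when adjusted over the list alone. That list did not pass camera with all arrays (adjusted p = 0.126, median log2 -0.10, 10 of 11 members lower), but did after quantile normalization (adjusted p = 0.0354, median log2 -0.08, adjusted p = 0.411 with an estimated correlation) and without the 3 arrays apart on the second component (adjusted p = 0.0019, median log2 -0.24, adjusted p = 0.569 with an estimated correlation). Pigment epithelium and melanin markers, which share 6 of its 11 members, passed in that last fit too (0.00159, adjusted p = 0.569 with an estimated correlation). The shifts of both lists correlated over the 6 chicks at 3 d (Pearson r = 0.828, against 0.421 at 6 h and 0.688 over all 12 chicks). One of those arrays, 3 d goggled replicate 3, had the highest mean of pigment epithelium and melanin markers of all arrays (9.04 on the log2 scale). With the chick as block, heat shock and unfolded protein response genes also passed camera at 3 d (adjusted p = 0.0342, 16 of 23 members higher, but adjusted p = 0.392 with an estimated correlation, and 0.126 without the block).

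**Figure D2:**
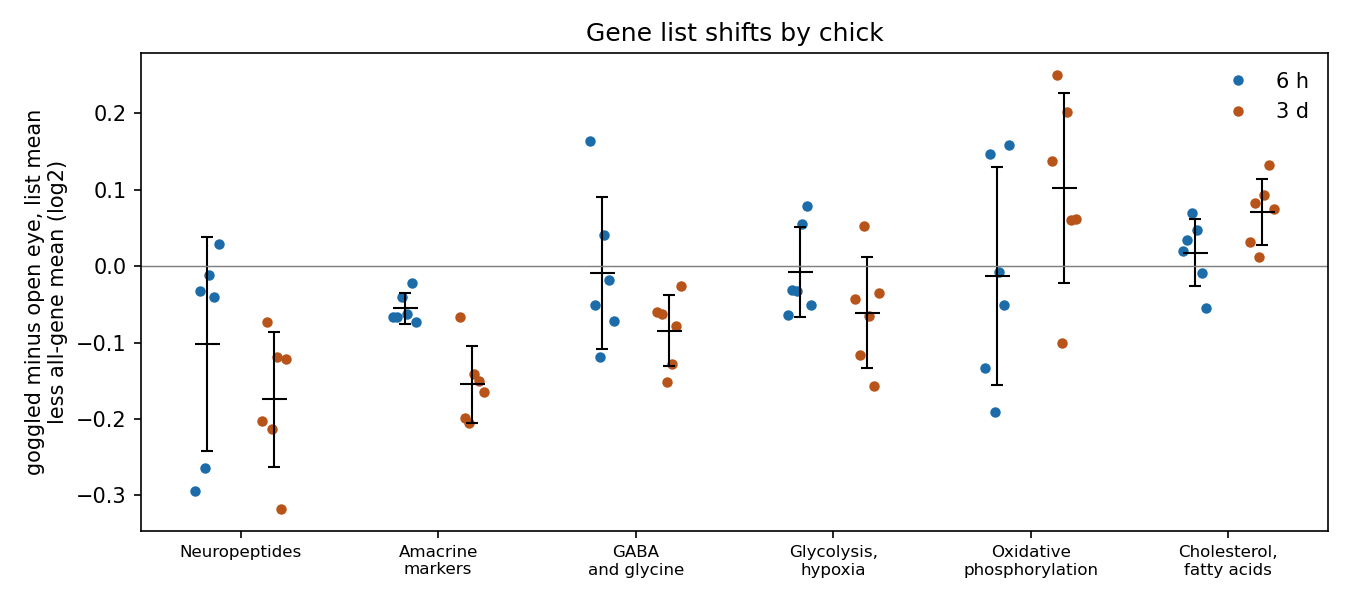
Goggled minus open eye in each chick for 6 gene lists, as the list's mean log2 difference less that of all genes, at 6 h and at 3 d, with bars for the mean ± SD of 6 chicks. At 3 d the neuropeptide, amacrine, and GABA and glycine lists were below 0 in 6 of 6 chicks, with an exact sign-flip adjusted p of 0.203 for each. With 6 chicks the unadjusted sign-flip p cannot go below 0.0312, so a few lists alone could not pass the adjustment.

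Goggled and open eyes at 6 h were compared for the early response. No probe set passed an adjusted p of 0.05 in limma, 635 had an unadjusted p under 0.05 against 1345 that chance would give, and with the chick as block the count was 0, with 1233 unadjusted. UTS2B and VIP were already lower in the goggled eye of all 6 chicks. UTS2B was 116.5 ± 17.2 (SD, n = 6) in open and 76.5 ± 11.4 in goggled eyes (log2 -0.52, limma adjusted p = 0.753), and VIP was 459.8 ± 133 against 285.1 ± 42.6 (log2 -0.63, limma adjusted p = 1, 6 of 6 lower). BMP2 was 299.4 ± 76 against 121.7 ± 43.9 and lower in 6 of 6 (log2 -1.22, limma adjusted p = 1). GCG was lower in 6 of 6 (log2 -0.32), TH in 5 of 6 (log2 -0.28) and the immediate early gene EGR1 in 5 of 6 (log2 -0.64, 553.3 ± 228 against 343.6 ± 107). Other genes with small p were FAAP100 (log2 0.47) and RNF214 (log2 0.46), higher in 6 of 6, and BRWD1 (log2 -0.38), AFAP1L1 (log2 -0.51) and MAGI2 (log2 -0.36), lower in 6 of 6. The other chosen genes had log2 differences of -0.45 (ALDH1A2), -0.15 (RBP4), -0.10 (TGFB2), 0.01 (NPY), 0.02 (PENK), 0.04 (DRD4), 0.05 (CRY1), 0.07 (EDNRB), 0.09 (NOG) and 0.09 (CRABP1). The ALDH1A2 value rested on 6 h control replicate 5, with a signal of 405.5 against 47.6 to 60.9 in the other open eyes, and this array had the highest choroid, sclera and vessel marker mean of its group (7.18 on the log2 scale). Without 6 h goggled replicate 1, 1 probe set was called.

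**Figure D3:**
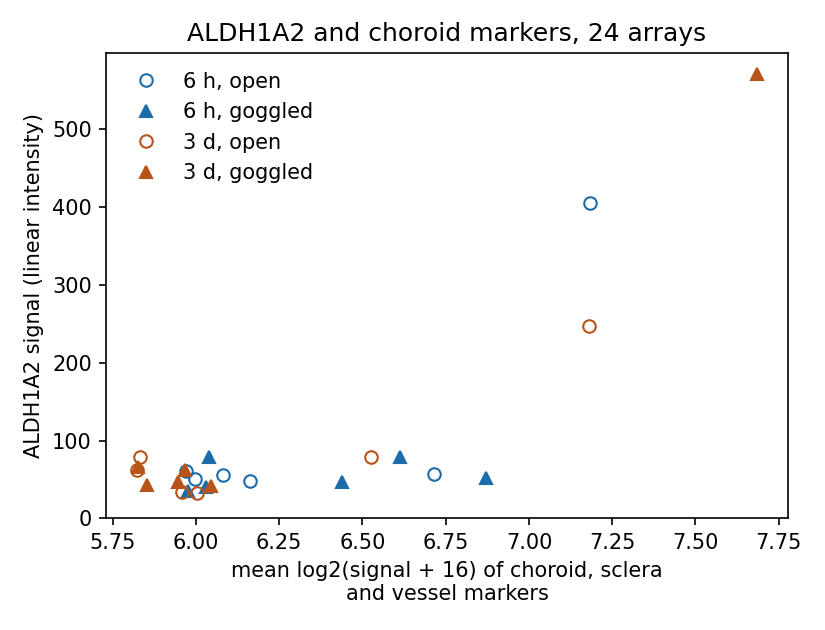
ALDH1A2 signal (linear intensity) against the mean log2 signal of 23 choroid, sclera and vessel markers on each of the 24 arrays, by group. The 3 arrays with the highest ALDH1A2 signal (571.3, 405.5 and 246.6) also had the 3 highest marker means.

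At 6 h the 21 neuropeptide genes had lower values in 14 (median log2 -0.05), and adjusted over the list alone UTS2B (adjusted p = 0.00117, lower in 6 of 6) and VIP (0.00253) fell in limma's test. Camera called the list at an adjusted p of 0.0327, against an adjusted p = 0.267 with an estimated correlation, 0.0636 with the chick as block and 0.0591 after quantile normalization (list mean lower in 5 of 6 chicks). All 11 genes of the retinoid cycle had lower values (median log2 -0.14), including RDH5 (log2 -0.34) and RGR (log2 -0.19), and camera's adjusted p was 0.0130, or an adjusted p = 0.537 with an estimated correlation. All 7 muscle markers of the iris and ciliary body had higher values (median log2 0.28), including the skeletal muscle genes TNNT3 and ACTA1 (log2 0.86), with a camera adjusted p of 0.00704, or an adjusted p = 0.537 with an estimated correlation. No member of these last lists passed, also adjusted over the list alone. The muscle markers were highest on goggled replicates 6 and 5, with means of 7.43 and 6.64 on the log2 scale against 5.65 to 5.97 in the other goggled eyes at 6 h. Without these 2 arrays camera's adjusted p was 0.827 for the muscle markers (median log2 0.02), 0.0875 for the retinoid cycle (median log2 -0.14) and 0.0875 for the neuropeptides (median log2 -0.07).

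Over both times together, VIP fell by 0.79 on the log2 scale (SE 0.10, limma adjusted p = 8.54e-04, lower in 12 of 12 chicks) and UTS2B by 0.66 (SE 0.08, adjusted p = 1.63e-04, lower in 12 of 12). BMP2 had a log2 difference of -1.25 (SE 0.23, lower in 11 of 12) and passed limma with the chick as block (adjusted p = 0.041) but not without it (adjusted p = 0.0665), and not with the block in at least 9 of 12 fits that left out both eyes of a chick. Its second probe set differed by -0.22. Limma thus called 2 probe sets, or 3 with the chick as block, with 1624 and 2599 at an unadjusted p under 0.05, and 11 with the chick as a random block (2 higher, 9 lower). Without 3 d goggled replicate 3, the array high in choroid markers, 6 were called.

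Among the genes that came next over both times, LBH, a regulator of transcription, was higher in 12 of 12 chicks, with a signal of 3616 ± 298 (SD, n = 6) in open and 4524 ± 303 in goggled eyes at 6 h, and 3779 ± 256 and 4722 ± 497 at 3 d (log2 0.32, limma adjusted p = 0.0665). BDNF, which encodes brain-derived neurotrophic factor, was lower in 12 of 12 (log2 -0.36, limma adjusted p = 0.119), and so was the adaptor gene SHC4 (log2 -0.38, limma adjusted p = 0.0698). DUSP4 was lower in 10 of 12 (log2 -0.51, limma adjusted p = 0.0698), and SPIRE1, a nucleator of actin filaments, in 10 of 12 (log2 -0.53, limma adjusted p = 0.608). CCN2, or connective tissue growth factor, was lower in 11 of 12 (log2 -0.98, limma adjusted p = 0.274), with the exception again in 3 d goggled replicate 3 (682.3 against 131.3 to 272.5 in the other goggled eyes at 3 d). NTS was higher in 12 of 12 (log2 0.37, limma adjusted p = 0.552).

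Camera called 12 lists over both times, of which the neuropeptides held with an estimated correlation (adjusted p = 0.00195 preset, adjusted p = 0.0245 with an estimated correlation, 15 of 21 lower, median log2 -0.10). This was lost with the chick as block (adjusted p = 0.213 with an estimated correlation) and after median centring (0.344). An exact sign-flip test over the 12 chicks, two-sided, called the neuropeptides (list mean lower in 11 of 12, adjusted p = 0.0285) and the amacrine markers (lower in 12 of 12, adjusted p = 0.019). The amacrine markers had a camera adjusted p of 0.00292, or an adjusted p = 0.269 with an estimated correlation, with 14 of 20 members lower. Their median was -0.03 on the log2 scale, or 0.01 after median centring, while their mean was -0.12. The other 10 calls were lost in both of these tests, with exact sign-flip adjusted p from 0.138 to 0.561. They were the retinoid cycle (11 of 11 lower, camera adjusted p = 0.00682, adjusted p = 0.269 with an estimated correlation), the muscle markers (7 of 7 higher, 0.00682 and 0.269), opsins outside image-forming vision (6 of 7 lower, 0.00921 and 0.246) and glycolysis (23 of 30 lower, 0.0140 and 0.269). Below these stood rod and cone markers (11 of 15 lower, 0.0293 and 0.344), oxidative phosphorylation (31 of 45 higher, 0.0432 and 0.765) and, at a preset adjusted p of 0.0451 each, GABA and glycine (17 of 22 lower, 0.269 with an estimated correlation, 0.0514 with the chick as block), glutamate signalling (14 of 17 lower, 0.269), phototransduction (17 of 25 lower, 0.580) and heat shock (15 of 23 higher, 0.269). Of these, median centring turned the median of the GABA and glycine list from -0.02 to 0.02. The muscle markers were highest on 6 h goggled replicates 6 and 5 and on 3 d goggled replicate 3. Their means there were 7.43, 6.64 and 6.73 on the log2 scale, against at most 5.97 on the other arrays.

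The difference of the goggle effect between 3 d and 6 h was tested to see which effects depend on the duration of wear. Limma called 0 probe sets, with 601 at an unadjusted p under 0.05, and 0 with the chick as block, with 1136 unadjusted, so that no single gene was shown to respond differently at the times. The smallest p were those of SHC4 (log2 0.66, on a probe set below background), ARHGEF37 (log2 1.28), EDEM3 (log2 -0.79), XRCC3 (log2 -0.71) and FBXO44 (log2 -0.66). ARHGEF37 and EDEM3 had 3 of 4 group means below background. As a group, the oxidative phosphorylation genes were shifted towards higher values at 3 d than at 6 h in 42 of 45 (median log2 0.10, camera adjusted p = 6.51e-06, but adjusted p = 0.801 with an estimated correlation). Amacrine markers were shifted towards lower values in 16 of 20 (median log2 -0.10, camera adjusted p = 0.0289, but adjusted p = 0.801 with an estimated correlation). The amacrine call was lost after median centring, at a camera adjusted p of 0.0537 (median log2 -0.07, 16 of 20 lower before centring). With the chick as block, glycolysis also passed (camera adjusted p = 0.0480, 22 of 30 lower, but adjusted p = 0.668 with an estimated correlation, and 0.0716 without the block).

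Open eyes at 3 d were compared with open eyes at 6 h, which sets different and differently aged chicks against each other, possibly taken at different times of day. CPLX4, a complexin of photoreceptor and bipolar cell ribbon synapses, rose from a signal of 1565 ± 129 (SD, n = 6) to 2383 ± 213, and PTMA, which encodes prothymosin alpha, fell from 3924 ± 469 to 1074 ± 362. Limma called 1970 of 26907 probe sets, 703 higher and 1267 lower (64.3% lower), of which 578 changed at least 1.5-fold. With only the 12 arrays compared 913 were called (72.1% lower), with 1 probe set per gene 676, and at an adjusted p under 0.10 3337. The split depended on the scaling: 53.2% were lower after quantile normalization (1721 called) and 34.1% after median centring (2095 called). Of the 1970 calls, 72.4% were also made after quantile normalization, all in the same direction, against 54.0% of the calls in goggled eyes described below. The PTMA fall (log2 -1.90, limma adjusted p = 4.89e-08, 6 arrays per group) was seen on 1 of its 4 probe sets, and the other 3 differed by -0.09 to -0.06. This held for many genes: where a called gene had other probe sets, 53.4% of those of risen genes and 65.4% of those of fallen genes went the same way, with 6.20% and 6.89% called in that direction and 25 and 38 probe sets called in the opposite one, so that changes in part of a transcript and of a whole gene were not separated.

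Photoreceptor and synapse genes were among those that rose between 6 h and 3 d in open eyes. Of 25 phototransduction genes, 18 had higher values (median log2 0.25), and 5 rose, 0 fell and 20 did not pass over all genes, or 9 rose and 2 fell adjusted over the list alone. GUCA1A, a guanylate cyclase activator, rose by a log2 of 0.75 (SE 0.18), CNGB1, a subunit of the rod channel, by 0.67, PDE6C, the cone phosphodiesterase, by 0.44 and PDC, or phosducin, by 0.36. Camera's adjusted p was 0.00259 for the list, or an adjusted p = 0.672 with an estimated correlation, and 0.229 after quantile normalization (median log2 0.21, 18 of 25 higher before it). Other genes of the outer retina and synapse that rose were CPLX4 (log2 0.60, SE 0.08), SV2B (log2 0.31), the pigment epithelium lactate transporter SLC16A8 (log2 0.42), the ON bipolar channel TRPM1 (log2 0.39) and the sodium channel SCN8A (log2 0.56). LNX1 (log2 0.29) and the ganglion cell gene SNCG (log2 0.42) rose too.

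Ribosomal protein genes had higher values at 3 d in 50 of 56 (median log2 0.16), and RPL23 (log2 0.82), RPLP1 (log2 0.29), RPL32 (log2 0.30) and RPL5 (log2 0.29) rose, while 52 did not pass. RPL23 and RPLP1 had other probe sets with differences as low as -0.35 and -0.67. Of 45 oxidative phosphorylation genes, 32 had higher values (median log2 0.11) and ATP5G1 (log2 0.40), NDUFB5 (log2 0.26) and NDUFS1 (log2 0.21) rose. Adjusted over the list alone, 4 ribosomal and 3 oxidative phosphorylation genes rose. Camera's adjusted p was 8.17e-07 for ribosomal proteins and 0.0119 for oxidative phosphorylation, each with an adjusted p = 0.672 with an estimated correlation. After quantile normalization neither list passed camera (adjusted p 0.38 with a median log2 of 0.06, and 0.427 with 0.07, against 50 of 56 and 32 of 45 members higher before it). Lipid synthesis had 5 genes that rose and 1 that fell of 27, including DHCR7 of cholesterol synthesis (log2 0.70), the sterol regulator SREBF2 (log2 0.58), the desaturase FADS2 (log2 0.57) and fatty acid synthase FASN (log2 0.45), with the elongase ELOVL6 lower (log2 -0.36). Adjusted over the list alone 6 rose and 2 fell, and the list did not pass camera (adjusted p = 0.113, 17 of 27 higher). The chaperones HSP90AB1 (log2 0.39), HSP90B1 (log2 0.38) and HSPD1 (log2 0.31) rose.

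Genes of inhibitory transmission were among those that fell in open eyes. Of 22 GABA and glycine genes, 4 fell: the GABA transporter SLC6A11 (log2 -0.52), the receptor subunits GLRB (log2 -0.47) and GABRA2 (log2 -0.47), and GABBR2 (log2 -0.42), and 18 did not pass. Adjusted over the list alone 5 fell and 1 rose, and the list did not pass camera (adjusted p = 0.272, 15 of 22 lower). Of acetylcholine receptors, CHRM5 (log2 -0.45) and CHRNA7 (log2 -0.32) fell and CHRNA4 (log2 0.47) rose. The FGF family gene FGF14 (log2 -0.67) and the growth factor gene VEGFA (log2 -0.60) fell. So did SPRED1 (log2 -0.31) and WNT11 (log2 -0.57), while IGF1R rose (log2 0.34). Matrix genes that fell were VCAN (log2 -0.51) and THBS1 (log2 -0.49), and the fallen glial and horizontal cell markers were the water channel AQP4 (log2 -0.46) and HAPLN1 (log2 -0.43). The opioid peptide gene PENK fell from 4678 ± 222 to 3743 ± 279 (log2 -0.32), and the calcium channel CACNA1D fell (log2 -0.37). Of the 22 clock genes, the repressor CRY1 fell (log2 -0.41) and PER3 rose (log2 0.52). One other probe set of CRY1 differed by 0.25.

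**Figure D4:**
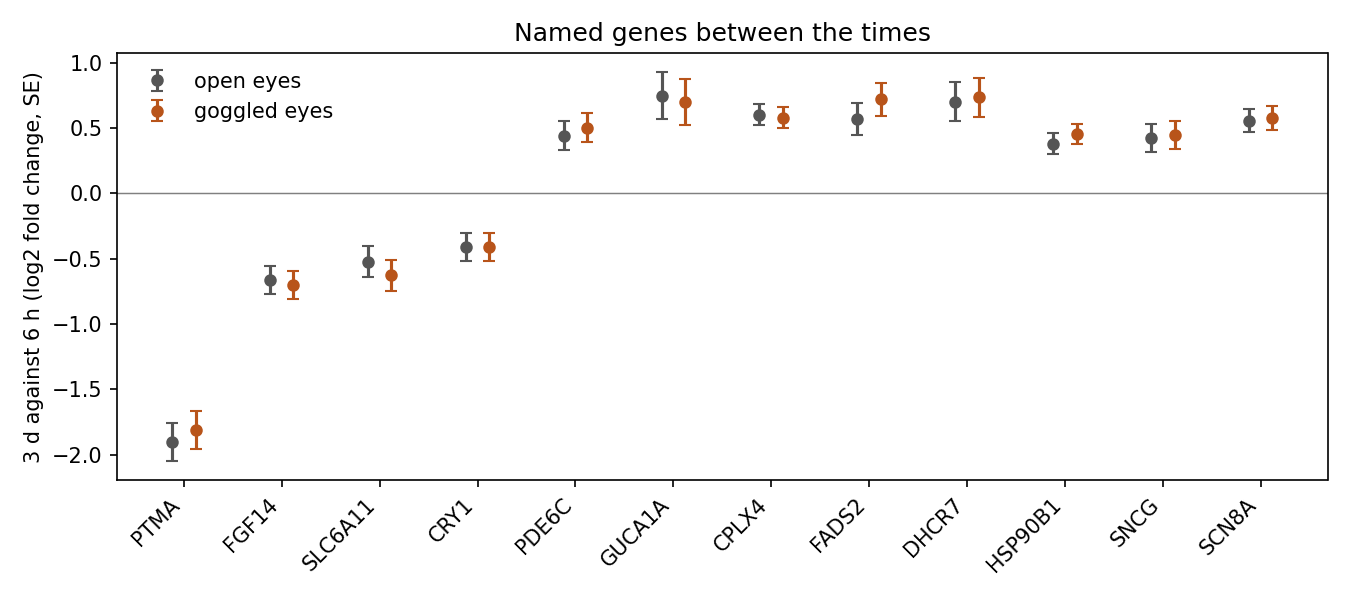
Log2 change from 6 h to 3 d (± SE) of 12 genes in open and in goggled eyes, 6 arrays per group. PTMA, FGF14, SLC6A11 and CRY1 were lower and the other 8 genes higher at 3 d in both kinds of eye.

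The 10 lowest and 10 highest named genes in open eyes lay mostly outside these lists. Besides PTMA, the lowest were KBTBD3 (log2 -1.45), MED27 (log2 -1.33), PRPF8 (log2 -1.28), CDK6 (log2 -1.25), SPTBN1 (log2 -1.21), LRCH2 (log2 -1.17), PSMB5 (log2 -1.15), VPS13D (log2 -1.14) and RAB43 (log2 -1.11). Besides RPL23, the highest were NTNG2 (log2 1.11), VAC14 (log2 1.07), FCGBP (log2 0.94), ARHGEF10L (log2 0.94), TRIM3 (log2 0.89), SEMA4G (log2 0.85), IQSEC3 (log2 0.84), the creatine transporter SLC6A8 (log2 0.82) and MNT (log2 0.81). Of these, all probe sets of KBTBD3, LRCH2, SPTBN1, NTNG2, TRIM3 and IQSEC3 went the same way, while those of MED27, PRPF8, RAB43 and SEMA4G did not. Mean signals at 3 d were below the 22.8 of background for MED27 (12.8), PRPF8 (10.7), CDK6 (9.27), VPS13D (8.70) and RAB43 (5.05), and at 6 h for VAC14 (12.0), FCGBP (21.4), TRIM3 (20.7), SEMA4G (17.7) and MNT, so that the size and rank of these changes depend on the offset added before log2. The same holds for CHRM5, VCAN and WNT11 above, with means of 14.2, 14.2 and 12.0 at 3 d.

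In goggled eyes, 3 d against 6 h gave 3416 called probe sets, 1110 higher and 2306 lower (67.5% lower), of which 967 changed at least 1.5-fold. After quantile normalization 2168 were called and 51.8% were lower, and after median centring 3397 and 32.5%. With 1 probe set per gene 1293 were called, and at an adjusted p under 0.10 5351. Median centring moved the median log2 change of all probe sets from -0.08 to 0.03, and the values below shift with it. PTMA (log2 -1.81, SE 0.15), PRPF8 (log2 -1.39), SPTBN1 (log2 -1.22) and MED27 (log2 -1.17) were again among the lowest, with USP30 (log2 -1.20), TFG (log2 -1.19), UQCRB (log2 -1.17), ZFP36L1 (log2 -1.17), HIPK2 (log2 -1.17) and HSPA9 (log2 -1.15). RPL23 (log2 1.01) and MNT (log2 0.91) were again among the highest, with GMPPB (log2 0.99), SAFB (log2 0.81, limma adjusted p = 1.24e-04, 6 arrays per group), ELP4 (log2 0.81), SRRL (log2 0.79), WWC1 (log2 0.79), the water channel AQP1 (log2 0.78), TLE3 (log2 0.76) and SNRPGP15 (log2 0.74). Mean signals were below background at 3 d for PRPF8 (10.6), MED27 (13.8) and HIPK2 (9.65) and at 6 h for MNT (10.5) and TLE3 (13.9), which limits the size of these values in the same way. Open and goggled eyes shared 496 risen and 840 fallen probe sets, against 29.0 and 109 for independent lists, with 0 called in opposite directions. Both kinds of eye come from the same chicks, which adds to this overlap. Where a gene called in goggled eyes had other probe sets, 46.7% of those of risen genes and 66.3% of those of fallen genes went the same way. Of the former 87 were called in that direction and 57 in the opposite one, and of the latter 240 and 74, so that the gene changes below hold for the probe set called.

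Of 45 oxidative phosphorylation genes, 11 rose in goggled eyes between 6 h and 3 d, or 15 adjusted over the list alone, and 40 had higher values (median log2 0.21). Examples were NDUFB9 (log2 0.47), ATP5G1 (log2 0.45), NDUFB5 (log2 0.38) and NDUFS1 (log2 0.35), against a UQCRB probe set that fell. Of 56 ribosomal protein genes 51 had higher values (median log2 0.20) and 7 rose, over all genes and adjusted over the list alone, including RPL36 (log2 0.44), RPL32 (log2 0.38) and RPLP1 (log2 0.36). Camera gave adjusted p of 2.62e-08 and 1.52e-08 for these lists, each with an adjusted p = 0.846 with an estimated correlation. Lipid synthesis had 7 genes that rose and 2 that fell of 27, or 9 and 4 adjusted over the list alone: DHCR7 (log2 0.74), FADS2 (log2 0.72), FASN (log2 0.37) and FDFT1 (log2 0.31) rose, and CYP51A1 (log2 -0.61) and ELOVL6 (log2 -0.44) fell. Camera's adjusted p for it was 0.0223 (18 of 27 higher, adjusted p = 0.354 with an estimated correlation), and 0.0805 after quantile normalization. The chaperones SERPINH1 (log2 0.65), HSPD1 (log2 0.46), HSP90B1 (log2 0.45) and HSP90AB1 (log2 0.42) rose, and CHAC1 (log2 -0.46) fell. CYP51A1 and CHAC1 had mean signals below background at 3 d (14.3 and 17.7).

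Some genes of inhibitory transmission and of light sensing changed in goggled eyes as well. Of 22 GABA and glycine genes 5 fell and 1 rose, or 6 and 1 adjusted over the list alone: GLRA1 (log2 -0.96), SLC6A11 (log2 -0.63), GABRA2 (log2 -0.58) and GLRB (log2 -0.49) fell and GLRA3 rose (log2 0.29). Camera's adjusted p was 0.0456 (18 of 22 lower, median log2 -0.14, adjusted p = 0.846 with an estimated correlation), and 0.072 after median centring. Of 25 phototransduction genes 5 rose and 1 fell, or 7 and 2 adjusted over the list alone: GUCA1A (log2 0.70), CNGB1 (log2 0.51), PDE6C (log2 0.50) and PDC (log2 0.32) rose and GNGT2 (log2 -0.45) fell. Their camera adjusted p was 0.0456 (16 of 25 higher, median log2 0.18, adjusted p = 0.846 with an estimated correlation), with 0.484 after quantile normalization and 0.0989 after median centring. ABCA4 (log2 0.40) and the retinol carrier RBP4 (log2 0.39) of the retinoid cycle and the retinoic acid binding protein CRABP1 (log2 0.60) rose.

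Single genes of other groups that changed in goggled eyes included the dopamine receptor DRD4, which rose (log2 0.35, limma adjusted p = 0.00751, 6 arrays per group), and DDC, which makes dopamine from its precursor and fell (log2 -0.39). Among amacrine markers TFAP2A (log2 -0.68) and SST1 (log2 -0.51) fell. The horizontal cell marker CALB1 (log2 0.63) and the glial glutamate transporter SLC1A3 (log2 0.30) rose, and the ganglion cell marker RBPMS2 (log2 -0.42) and the glial AQP4 (log2 -0.49) fell. Neurocan, NCAN (log2 -0.85), and COL5A2 (log2 -0.60) fell, and the metalloproteinase inhibitors TIMP3 (log2 0.56) and TIMP2 (log2 0.51) rose. The channel gene KCNJ3 (log2 -0.78), the FGF family genes FGF14 (log2 -0.70) and FGF2 (log2 -0.38) and the BMP inhibitor SMAD7 (log2 -0.40) fell. So did the immediate early genes JUN (log2 -0.39) and SIK1 (log2 -0.36). FGF9 (log2 0.34) and the WNT antagonists DKK3 (log2 0.27) and SFRP1 (log2 0.24) rose. CRY1 fell (log2 -0.41) and RORA rose (log2 0.26), and the metabolic genes PDK1 (log2 -0.24) and LDHB (log2 0.23) went in opposite directions. None of these genes was shown to change differently in goggled and open eyes, since limma called 0 probe sets for that difference, with 601 at an unadjusted p under 0.05.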

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

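The tests of RNA quality, of array scaling and of amacrine cell number were chosen only after the results they address had been seen, and so were the sign-flip tests of lists, after camera's calls.

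Camera called 8 lists in goggled eyes at 3 d with its preset correlation, of which with an estimated one the neuropeptides alone held (adjusted p = 0.0404, against 0.225 for amacrine, glycolysis and lipid genes), or with the chick as block the amacrine markers alone (0.0353, against 0.316 for the neuropeptides), and the difference between the times was called for oxidative phosphorylation (6.51e-06) and amacrine markers (0.0289), each with an adjusted p = 0.801 with an estimated correlation. Fewer amacrine cells in the goggled sample would lower all their markers by about the change in GAD2, TH and VIP. The median of the 14 amacrine markers that are not neuropeptides was -0.0495 on the log2 scale, above the -0.29 of GAD2, the smallest of those falls. Its bootstrap interval was -0.150 to -0.00138, drawn over markers and not over chicks. The bound was set after GAD2, TH and VIP had been seen to fall, and GAD2 and TH are among the 14. The median marker thus fell less than GAD2, but the test cannot decide on a loss of cells. Genes of a list moving together from eye to eye regardless of the goggle stay a candidate explanation: in the exact sign-flip test over 6 chicks, 4 of the 8 lists called had the smallest possible p of 0.0312 and the other 4 a higher one. No list passed this sign-flip test once adjusted over the lists, where the lowest p was 0.203. The adjusted result cannot decide between a goggle effect and genes moving together, since with 6 chicks the sign-flip p cannot go below 0.0312. A list could pass the adjustment only if many lists had that smallest p at once. RNA quality was not shown to differ and stays open: the actin ratio, goggled less open eyes, had a log2 difference of 0.05 with an SE of 0.08 (higher in 4 of 6 chicks, exact sign-flip p = 0.656). An effect of the goggle on these genes stays among the open explanations.

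Eyes of 3 d chicks differed from those of 6 h chicks at 1970 probe sets in open eyes and 3416 in goggled eyes. Array scaling as the whole cause is argued against by the 72.4% of the calls in open eyes that were also made after quantile normalization, all in the same direction, while in goggled eyes the share was 54.0%, so that scaling as a cause of part of the calls stays open. Time of day of tissue collection stays open. Goggles were fitted at the start of the light phase, so retinas taken 6 h and 3 d later may come from different times of day. The clock genes cannot decide this, because the interval of their odds ratio is wide. Of 22 clock genes 2 were called, against 667 of 11095 others, an odds ratio of 1.56 with an interval of 0.177 to 6.46 (one-sided Fisher's exact p = 0.385). RNA quality stays open too, since its actin ratio had a log2 difference between the times of 0.13 with an SE of 0.15 (exact permutation p = 0.452). Age and the duration of the experiment were not tested separately, because each time has its own chicks.

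ALDH1A2, a retinoic acid synthesising enzyme, was far above the other arrays of the group in 6 h control replicate 5 (gap of 0.9 of the range on the log2 scale) and 3 d goggled replicate 3 (0.848). Choroid, sclera or vessel tissue carried over may be the source: on these 2 arrays the mean of 23 tested choroid, sclera and vessel markers was the highest of its group, with 11 and 20 markers above all other arrays of the group, where chance gives 16.7% of them. The abundant markers COL3A1 and DCN were 1565.8 and 1470.6 on 3 d goggled replicate 3, against at most 68 and 55.3 in the other goggled eyes at 3 d, and 556.3 and 872.3 on 6 h control replicate 5, against at most 91.7 and 379.9 in the other open eyes at 6 h, while the most abundant marker of the list, SLC2A1, was 3926.9 on the former, against 3081.8 to 3923.4 in the other goggled eyes at 3 d. Against this source, DCN was also high on 6 h control replicate 1 (379.9) and 6 h goggled replicate 5 (539.1), with marker means of 6.71 and 6.87 on the log2 scale, while ALDH1A2 was 56.6 and 51.8 there. VWF was high there too (267.7 and 177.5), but MYH11 (41.4 and 24.2) and TAGLN (24 and 39.7) were not. On 6 h control replicate 5, 3 d control replicate 2 (ALDH1A2 246.6) and 3 d goggled replicate 3, MYH11 was 175.8, 198.9 and 290.7 and TAGLN 138.4, 175.3 and 197.9. ALDH1A2 thus went with some markers of the list and not with others, so that the test does not show where it comes from. Of the 32 genes of the list, 13 are also in other lists, and no biological explanation for single eyes was tested.

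Across the named genes, 30 of 406 groups of 6 arrays had an array far from the others, where chance flags about 1 in 20 groups, or 20.3. Each is given as its gap to the nearest array over the group's range. Among arrays of open eyes at 6 h, EDNRB was high in replicate 1 (0.719, signal 434.9 against 16.9 to 52.6), BRWD1 in replicate 4 (0.709), VAC14 in replicate 2 (0.699) and GUCA1A in replicate 3 (0.646). Low were CDK6 (0.637), ELOVL6 (0.721) and SPRED1 (0.654) in replicate 3, PSMB5 in replicate 1 (0.628), THBS1 in replicate 4 (0.679) and HSP90AB1 in replicate 2 (0.661). Among goggled eyes at 6 h, EDNRB was high in replicate 5 (0.678, signal 485.2 against 21.6 to 70.6), and low were BRWD1 in replicate 2 (0.649), JUN in replicate 6 (0.743), and SLC6A11 (0.634), GABRA2 (0.835, signal 666.2 against 955.7 to 1026.1) and GLRA3 (0.711) in replicate 4. Among open eyes at 3 d, CDK6 was high (0.642) and EDNRB low (0.643) in replicate 6, and PDE6C low in replicate 2 (0.632). Among goggled eyes at 3 d, TGFB2 was high in replicate 3 (0.762), and PENK (0.646) and SLC16A8 (0.663) in replicate 4. HIPK2 (0.639) and DKK3 (0.7) were high in replicate 6, where UTS2B (0.652), SLC6A11 (0.657) and SLC1A3 (0.627) were low. HSPA9 was high in replicate 1 (0.768, signal 1124.2 against 289.9 to 399.3). The open eye of that chick was high in HSPA9 too, with 1150.7 against 251.7 to 368.3 in the other open eyes at 3 d. The high HSPA9 signal was thus not confined to the goggled eye.

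Among the named genes, the goggle effects of 3 were opposite at the times in all 6 chicks of each. LRP3 differed by 0.48 at 6 h and -0.40 at 3 d, a change of -0.885, CENPU by 0.29 and -0.31 (-0.606), and PTGR2 by -0.20 and 0.30 (0.498), all on the log2 scale. Mean signals of LRP3 and CENPU were below the 22.8 of background in 2 of 4 groups each (lowest 13.9 and 15.8), so that the size of their differences depends on the offset added before log2. Limma's test of this difference gave an adjusted p of 1 for each, and 0.681, 0.835 and 0.885 with the chick as block.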

How the results depend on the processing

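The tests with other offsets, with a W-linked covariate, without both eyes of a chick, without arrays that stood apart, of lists under other scalings and by sign-flip were chosen only after the results had been seen. No called gene and no camera direction of a called list reversed in the alternatives run on them. Median centring turned the majority of the calls between the times from lower to higher (34.1% lower in open eyes and 32.5% in goggled eyes), and the list medians over both times of GABA and glycine genes (to 0.01616) and amacrine markers (to 0.01332), and the amacrine median at 3 d turned without the 3 arrays apart (to 0.003472). In all 6 comparisons, the number of probe sets called kept within 1.5 times its value under no filter, trended robust variances, median centring, the 1.2-fold minimum and offsets of 1 and 8. So it did with the W-linked covariate in the 2 comparisons between the times, and without the 3 arrays apart in these and in the goggle comparison at 3 d, where, however, VIP was no longer among the 2 calls at 3 d (limma adjusted p = 0.215). The cause of the other changes was not tested, except that 1 probe set per gene tests fewer probe sets and an adjusted p under 0.10 is a looser threshold.

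With 1 probe set per gene, open eyes between the times gave 676 calls and goggled eyes 1293, and with only the 12 arrays compared open eyes gave 913. After quantile normalization goggled eyes between the times gave 2168 and the goggle comparison at 3 d 1. At an adjusted p under 0.10 the counts were 3337 in open eyes and 5351 in goggled eyes between the times and 7 for the goggle over both times. The latter count was also 7 with 1 probe set per gene, 6 with the filter at the 50th percentile, 5 with array weights and 4 with offsets of 32 and of 64. The fixed replicate block changed no count by more than 1.5 times, and it changed the calls given in the report: BMP2 over both times, 4 list calls lost and 2 gained with the preset correlation, and with an estimated correlation the neuropeptides lost at 3 d (0.316) and over both times (0.213) and the amacrine markers gained at 3 d (0.0353). With it fry called more lists, among them the amacrine markers at 3 d. As a random replicate block (correlation 0.263) it gave 4 calls at 3 d and 11 over both times, and the replicate block with only the 12 arrays compared gave 1 at 3 d, without UTS2B (limma adjusted p = 0.288). With the replicate block and without both eyes of a chick, the count at 3 d was 4 without replicate 1 and 1 without replicate 4, 5 or 6. UTS2B was called only without replicate 2, with limma adjusted p of 0.0515 to 0.167 without another, while VIP was called each time. Over both times the count was 5 without 3 d replicate 1, 4 without 3 d replicate 3 and 5 without 6 h replicate 1, and 2, VIP and UTS2B without BMP2, in the other 9 fits.

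Leaving out each array in turn gave 0 to 1 calls for the goggle at 6 h (1 without 6 h goggled replicate 1), 1 to 4 at 3 d (4 without 3 d control replicate 1, and 1 without 3 d control replicate 2, 3 d control replicate 5 or 3 d goggled replicate 4), 2 to 6 over both times (6 without 3 d goggled replicate 3), 0 for the difference of the effects, 1348 to 2189 in open eyes and 2481 to 3335 in goggled eyes between the times. For the difference, limma had 601 probe sets at an unadjusted p under 0.05 with all arrays.

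Of the named gene results, 51 no longer passed with only the 12 arrays compared, 48 after quantile normalization (1 newly passed), 40 after median centring, 27 without the filter, 7 with trended robust variances (1 newly passed) and 6 with array weights (3 newly passed), and the block let 1 more pass. Of the list results, 31 lost their call with an estimated correlation, 28 with fry, 11 after quantile normalization (3 gained), 10 with the mean of all probe sets of a gene (7 gained), 8 after median centring (1 gained), 8 without the filter (1 gained) and 10 in the sign-flip test. Without the 3 arrays apart on the second component 2 lists lost their call at 3 d and 3 gained one, among them pigment epithelium and melanin markers (camera adjusted p = 0.00159, adjusted p = 0.569 with an estimated correlation), and without the 2 arrays high in muscle markers 3 lost it at 6 h. Signal over background limits what can be seen, since 14.3% of the tested probe sets had a mean below the 95th percentile of the reporter probe sets (22.8), among them the EDEM3 result at 3 d.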

Other observations

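The genes named in the next paragraph were picked after their values were seen, from tests of whole lists that were fixed before, while no tests in this part were chosen after their result was seen.

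Beyond the groups described so far, single growth factor and signalling genes stood out within their lists over both times in limma's test adjusted over the list alone. BDNF fell among 35 genes of FGF, IGF, insulin and neurotrophin signalling (log2 -0.36, SE 0.07, adjusted p = 0.00124, lower in 12 of 12 chicks). CCN2 fell among 36 matrix genes (log2 -0.98, SE 0.21, adjusted p = 0.00403, lower in 11 of 12) and BMP2 among 36 genes of TGF-beta and BMP signalling (log2 -1.25, SE 0.23, adjusted p = 3.76e-04, lower in 11 of 12). The signalling gene WNT9A rose among 25 genes of WNT and hedgehog signalling (log2 0.57, SE 0.13, adjusted p = 0.00571, higher in 10 of 12). DUSP4 and the kinase SGK1 fell among 18 immediate early genes (log2 -0.42 and -0.20 on the brightest probe sets, adjusted p = 0.0371 and 0.0411, lower in 10 and 11 of 12), and the squalene synthase gene FDFT1 rose among 27 genes of lipid synthesis (log2 0.21, SE 0.06, adjusted p = 0.0412, higher in 12 of 12). TH fell among 14 dopamine genes (log2 -0.39, SE 0.08, adjusted p = 9.59e-04, lower in 11 of 12). None of these 7 lists passed camera over both times (adjusted p from 0.0826 to 0.926).

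A goggle effect shared by both times is a candidate explanation for the likeness of the goggle effects at 6 h and 3 d. Across 11117 genes, which are not independent replicates, the log2 differences at the times, from different chicks, correlated with a Pearson r of 0.215 and a Spearman rho of 0.231. Of all sign flips of the chicks, the real one included, 56 gave an r as high (exact one-sided p = 0.0273), and in the others r reached 0.317 or more. Of the 100 genes with the smallest p at 3 d, 70 had the same sign at 6 h. That count does not stand out, since a sign flip of the 6 h chicks gave 72, and not all flips were counted. The test of the correlation argues for a shared effect without naming its genes, while the count of signs does not.

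Other splits of the arrays were counted for each comparison. For open eyes between the times, chance can be excluded, since 1 of 100 splits, the real one, gave as many calls (1970 against 390 for the highest other), and likewise for goggled eyes, with 1 of 100 (3416 against 3). The split with 390 calls exchanged 1 array per group and so kept 5 of 6 arrays of each time together. For the goggle over both times and at 3 d, the splits also argue against chance without excluding it. The real count was 2 in each, and the shares were not adjusted over the comparisons. Over both times 3 of 100 splits gave as many calls as the real 2, the highest other being 2. Of 100 splits that part all pairs 1 did, the real one, with 1 as the highest other. At 3 d, 2 of 100 splits gave as many as the real 2, and of the 32 splits that part all pairs only the real one did, with 0 in the others, which exchange the eyes of some chicks. The other of those 2 splits called 51 probe sets, many more than the real one, which points to a structure of the arrays that does not follow the goggle: it parted both eyes of replicates 1, 4 and 5 from both eyes of replicates 2, 3 and 6. Both 3 d chicks with a low signal of a W-linked probe set, replicates 1 and 5 (37.5 to 127.1 against 5403.4 to 7063.3), were on the same side, together with replicate 4, which had a high one. For the goggle at 6 h, where limma called 0 and 635 probe sets had an unadjusted p under 0.05, the splits say nothing about chance, since every split gives at least 0 calls (100 of 100, with 3 in the highest other, and 32 of 32 that part all pairs, with 0). For the difference of the goggle effects, with 0 calls and 601 unadjusted, the same holds, with 1 in the highest of the other splits.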
